A study of Mus musculus with 6 samples.

How the data were processed

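Satellite cells were sorted by yellow fluorescent protein from injured hindlimb muscle, and RNA was sequenced after reverse transcription and amplification by the Smart-Seq2 protocol, per the labels' protocols. Smart-Seq2 starts from the poly(A) tail and does not mark the strand of the RNA. There were 3 libraries of controls and 3 labelled Paxbp1-iKO, grouped by their titles. The submitters' processing notes name Trim Galore, STAR, featureCounts of Subread, DESeq2 and the mouse build mm10 (GRCm38), without versions, roles or order. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here, so genes that overlap, antisense genes and genes with near-identical copies carry that uncertainty.

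The authors deposited a table of raw read counts per gene and library and a table of FPKM values (fragments scaled to gene length and library size) for the same genes. The deposited FPKM were scaled by median-of-ratios size factors instead of library totals: between any pair of libraries the ratio of count to FPKM matched the ratio of such size factors to within 9.3e-15 over the 11966 genes with at least 20 counts in every library. The count table had 46078 rows, of which 551 had no gene name. These held 0.108% to 0.123% of the counts of a library and were left out of library sizes and tests. Of the 45527 named rows, 45014 matched a gene symbol of GENCODE M21, from which positions, gene classes, exon lengths and GC content were taken; all gene lists were matched by symbol, with older symbols where needed.

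Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM factors, and a quasi-likelihood model with the group as its only term was fitted to all 6 libraries. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all 16252 tested genes were called, and counts adjusted over a list alone use only that list's members. CPM are relative to the TMM-scaled library size. Gene lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over 35 lists, and again with an estimated correlation. Fry, which tests whether a list's genes move on balance in a common direction, called 18 lists. Unlike camera, it called BCL2 family and caspase genes (higher, fry adjusted p = 0.0144), mTORC1 genes (higher, 0.048) and autophagy and lysosome genes (lower, 0.0203). Cytosolic ribosomal proteins, which camera called, were not called by fry (adjusted p = 0.263). Of the 26 gene lists and 11 marker lists, the satellite cell markers share 6 genes with the quiescence list and 5 with the differentiation list, and the matrix list shares 5 with the fibro-adipogenic markers.

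The groups, tests, gene lists, marker lists, alternatives and the rule for named genes were fixed before the data were examined. That rule takes Paxbp1 with Pax7, Myf5, Myod1, Myog, Cdkn1a, Trp53, Ccnd1, Mki67, Myc and Mtor, then the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 3, non-overlapping groups and a symbol that is not a predicted gene model, then up to 4 members of each gene list with the smallest adjusted p and up to 3 members of each marker list with the highest mean log2 CPM. A few of the genes that the rule takes from the lists are given only in the counts, and genes outside it are marked where they appear. For 6 genes, 3 taken by the rule and 3 singled out later, values are not reported here, and no other gene took their place; they stay in all tests, lists and gene counts, but not in the counts of results for named genes. The alternatives tried were DESeq2, RLE and upper-quartile factors, no count filter and a filter of at least 5 CPM in 3 libraries, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1, limma on log2(FPKM + 1) without a filter, a test against a 1.5-fold change, the replicate number as a block, mitochondrial genes and the 50 most abundant genes left out, and each library left out in turn. Chosen after seeing the data were scaling by library totals and the removal of trends on GC content and exon length.

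Versions of the other tools were DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The test was tested on simulated data: counts were drawn for the real genes from their means over the 6 libraries and the real library sizes with 200 genes changed, and 14725 genes passed the filter. It recovered 10 of 67 genes planted at 1.5-fold (14.9%), 30 of 67 at 2-fold (44.8%) and 48 of 66 at 4-fold (72.7%), with 12 false calls among 100, and made 0 calls with nothing planted. A planted list was recovered and 0 of the other lists, of 34 tested, were called. The simulated genes were drawn independently of each other, so this cannot show how often camera calls lists of correlated genes wrongly. Far more genes were called in the data than were planted here, which makes the adjusted threshold less strict there, so these shares need not hold. With 3 libraries per group and total counts between 23327359 and 28050748, smaller changes and changes in genes of few counts can still have been missed.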

Results

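Gene expression was measured by RNA sequencing in satellite cells, the Pax7-expressing stem cells of skeletal muscle, 24 h after the lower hindlimb muscles of mice had been injected with 30 µl of cardiotoxin, a venom toxin that kills muscle fibres and sets off regeneration. All mice carried a tamoxifen-inducible Cre recombinase under the Pax7 promoter and a Cre-activated yellow fluorescent protein, by which the cells were sorted. The 3 control libraries came from mice with 1 floxed and 1 wild-type allele of Paxbp1, and the 3 Paxbp1-iKO (inducible knockout) libraries from mice with both alleles floxed. Total counts per library were 23508654, 27198506 and 27309423 for controls 1 to 3 and 27710766, 28050748 and 23327359 for iKO 1 to 3. A count was present for 24334, 20508 and 20393 named genes in the controls and for 24256, 22964 and 25433 in the iKO libraries. Correlations of log2 CPM (counts scaled to library size) across the tested genes were 0.933 to 0.957 within groups and 0.902 to 0.924 between them, with genes not being independent replicates. The first principal component held 42.5% of the variance and separated the groups. Replicates of a group differed by more than counting noise (chi-square per degree of freedom 19.5 to 29.3), so no library was a repeat count of another. The labels speak of mice but do not tie each library to an animal, so p-values measure only the spread between these libraries. Levels are given as mean ± SD of CPM (n = 3 per group), fold changes as log2 of iKO-labelled against control ± SE, and p-values are Benjamini-Hochberg adjusted values from edgeR's quasi-likelihood test over all tested genes.

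The targeted gene was examined first, as a check of the labels. Paxbp1, which encodes a protein that binds the transcription factors Pax3 and Pax7 (ENSMUSG00000022974.12, minus strand of chromosome 16, 91014037 to 91044543 in GRCm38, 18 exons in the annotation), was higher in the libraries labelled Paxbp1-iKO, rising from 68.6 ± 6.81 to 110.2 ± 15.4 CPM (0.68 ± 0.13, adjusted p = 0.00954). Its counts were 1583, 1917 and 1592 in controls 1 to 3 and 2745, 3162 and 3125 in iKO 1 to 3, so that every iKO-labelled library lay above every control. This direction goes against the label of a knockout. Counts were made over the whole gene, and which exons are floxed is not given in the sources used here, so these values cannot show whether the floxed part was deleted. Groups are therefore called by their labels, and every direction below is drawn from those labels: "iKO-labelled" stands for the libraries labelled Paxbp1-iKO.

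**Figure D1:**
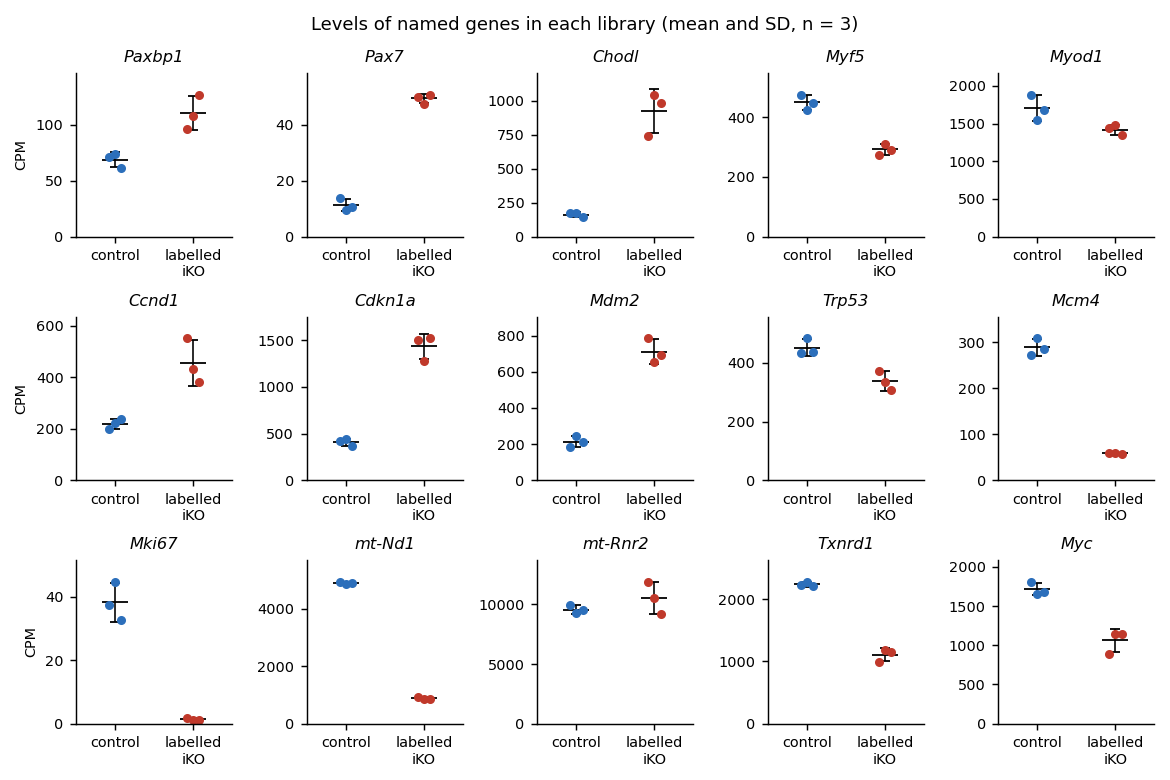
CPM of 15 named genes in each of the 3 control libraries (blue) and the 3 libraries labelled Paxbp1-iKO (red), with the mean and SD of each group as black bars and a linear axis from 0. Paxbp1 was higher in the iKO-labelled group (110.2 against 68.6 CPM), Mki67 and Mcm4 were lower, and the groups overlapped for mt-Rnr2.

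The comparison of the groups addresses what loss of Paxbp1 does to satellite cells as they re-enter the cell cycle after injury. The controls also carried the Cre recombinase and 1 floxed allele, so their cells need not have had both alleles intact. In the iKO-labelled libraries, genes of DNA replication and mitosis were lower, as were the messenger RNAs of the mitochondrial genome. Targets of the transcription factor p53 were higher, as was the satellite cell factor Pax7, which rose from 11.3 ± 2.14 to 49.5 ± 1.7 CPM (2.13 ± 0.17, adjusted p = 2.2e-04). The largest fall named by rule was that of Bub1, a kinase of the spindle checkpoint, from 23.2 ± 9.84 to 0.0725 ± 0.0686 CPM (-8.23 ± 0.69), and the largest rise that of Stox2, a winged-helix DNA-binding protein, from 3.12 ± 2.39 to 37.2 ± 9.69 CPM (3.58 ± 0.65). Ak1, an adenylate kinase, was level with Stox2 (3.57). Over the alternatives Stox2 ran from 1.77 to 4.14 and Ak1 from 3.26 to 3.81, so their order is not settled. Of 16252 genes tested, 3315 changed, 1324 of them higher and 1991 lower in the iKO-labelled group. The groups did not overlap for 3311 of the changed genes and for 6474 of all tested genes (39.8%, where chance gives 10%). Scaled by library totals alone, an alternative chosen after seeing the data, the split was 1921 higher (57.2%, against 39.9% with TMM) and 1440 lower, since that scaling moves the median of all genes by 0.13 on the log2 scale. DESeq2 called 2081 genes higher, and 817 genes changed when tested against a 1.5-fold change. The counts fell to 2053 without iKO 2 and 2103 without iKO 3, and those of higher genes to 845, 706 and 732 without iKO 1, 2 and 3.

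**Figure D2:**
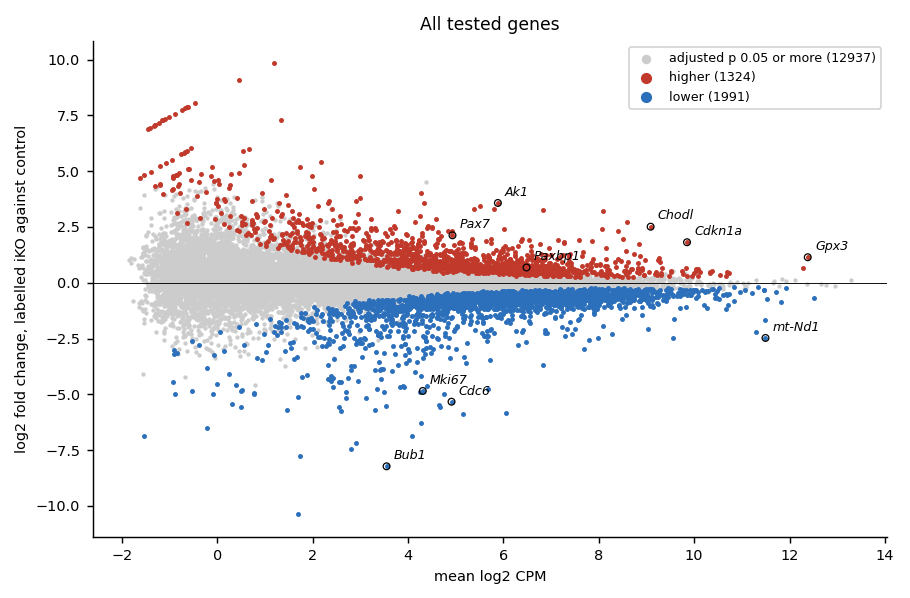
Log2 fold change of the libraries labelled Paxbp1-iKO against control for each of the 16252 tested genes, against mean log2 CPM over the 6 libraries. Red points are the 1324 genes higher and blue points the 1991 genes lower at an adjusted p under 0.05, and 10 named genes are circled.

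DNA replication and G1/S genes were lower. Of 40 tested, 37 fell and none rose, with a median log2 fold change of -2.21. Rises numbered 0 and falls 40 adjusted over the list alone. Mcm4, a subunit of the replicative helicase, fell from 289 ± 18.4 to 58.2 ± 0.366 CPM (-2.31 ± 0.083, adjusted p = 1.5e-05), and Rrm2, the regulatory subunit of ribonucleotide reductase, from 365 ± 58.7 to 46.6 ± 5.1 CPM (-2.97 ± 0.14). Uhrf1, which recruits the maintenance DNA methyltransferase, changed by -3.67 ± 0.17, and Cdc6, which loads the helicase at origins, by -5.33 ± 0.27. Camera, which compares a list with all other genes, placed this list lower (adjusted p = 1.4e-76, and adjusted p = 0.0439 with an estimated correlation). Of 30 G2/M and mitosis genes, 25 fell and none rose, with a median of -3.35. Rises numbered 0 and falls 27 adjusted over the list alone. Mki67, the proliferation marker Ki-67, went from 38.2 ± 6.11 to 1.32 ± 0.385 CPM (-4.85 ± 0.27, adjusted p = 6.6e-05), with values from -5.12 to -2.05 over the alternatives. The kinesin Kif11 (-4.92 ± 0.28), the midzone bundling protein Prc1 (-3.39 ± 0.23), Top2a, the topoisomerase of chromosome condensation (-5.86 ± 0.55), and Aurkb, the kinase of the chromosomal passenger complex (-6.85 ± 0.62), fell as well. The size of such folds depends on the processing: Aurkb ran from -7.62 to -3.45 over the alternatives. Camera gave adjusted p = 5.2e-33 for this list, a call lost at adjusted p = 0.0655 with an estimated correlation.

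Other genes of dividing cells made up the rest of the largest falls named by rule: Mybl2, a transcription factor of S phase (-6.31 ± 0.47), Pclaf, a partner of the sliding clamp (-5.90 ± 0.27), Esco2, the acetyltransferase of sister chromatid cohesion (-5.70 ± 0.64), Pbk, a mitotic kinase (-5.55 ± 0.59), Shcbp1 (-5.53 ± 0.40) and Anln, the anillin of the cleavage furrow (-5.48 ± 0.78). Levels of these genes and of Bub1 in the iKO-labelled libraries were near 1 CPM or below, so the size of each fold rests on few counts there (for Bub1 0, 4 and 2 counts). Cyclin D1 went the other way: Ccnd1, the cyclin of G1 entry, rose from 219.6 ± 19.4 to 456 ± 88.4 CPM (1.05 ± 0.14, adjusted p = 0.00187). Myc, a growth-promoting transcription factor, fell from 1719 ± 81.7 to 1065 ± 147 CPM (-0.69 ± 0.10, adjusted p = 0.00277). Among 30 DNA damage response and repair genes 15 fell and 1 rose, with a median of -0.79 (camera adjusted p = 6.6e-08, and adjusted p = 0.0439 with an estimated correlation). Rises numbered 1 and falls 20 adjusted over the list alone. Among the members with the smallest p were the Fanconi anaemia genes Fanca (-4.45 ± 0.48) and Fancd2 (-2.18 ± 0.29). The member that rose was Nbn, a sensor of double-strand breaks, singled out after its value was seen (0.54 ± 0.14, adjusted p = 0.0304). Its call ended without controls 1 or 2 or iKO 1 or 3 (adjusted p up to 0.101). On log2(FPKM + 1) without a filter the fall of Fancd2 was not called (adjusted p = 0.0801).

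Targets of p53 were higher. Of 33 tested, 23 rose and 1 fell, with a median of 0.96 (camera adjusted p = 2.9e-27, and adjusted p = 0.0439 with an estimated correlation). Rises numbered 24 and falls 1 adjusted over the list alone. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 408 ± 37.5 to 1437 ± 133 CPM (1.81 ± 0.10, adjusted p = 5.2e-05), and Mdm2, the ubiquitin ligase that degrades p53, from 213 ± 31.1 to 712 ± 68.2 CPM (1.74 ± 0.12). Phlda3, a repressor of Akt signalling (2.71 ± 0.13), cyclin G1 (Ccng1, 2.40 ± 0.15) and Ak1, an adenylate kinase (3.57 ± 0.26), rose too, and Gtse1, a protein of G2 that binds p53, was among the largest rises by rule (3.24 ± 0.30). The member that fell, singled out after its value was seen, was Gadd45a (-0.44 ± 0.11, adjusted p = 0.026). Its call ended under 7 of 19 alternatives (adjusted p up to 0.105). Among these were each control left out in turn, iKO 2 left out (adjusted p up to 0.0843 for these), and upper-quartile and library-total scaling. The messenger RNA of p53 itself, Trp53, fell from 452 ± 28.7 to 338 ± 33.1 CPM (-0.42 ± 0.09, adjusted p = 0.0147), a call that ended without control 2, iKO 2 or iKO 3 (adjusted p up to 0.0615) and on unfiltered log2(FPKM + 1). Of 27 BCL2 family and caspase genes, 6 rose and 3 fell, and camera did not call the list (adjusted p = 0.108). Rises numbered 6 and falls 3 adjusted over the list alone. The risers with the smallest p were Pmaip1 (1.92 ± 0.14) and Apaf1 (1.76 ± 0.25), which promote mitochondrial apoptosis, Mcl1, which opposes it (0.51 ± 0.085), and Bax (0.49 ± 0.091); 5 members, among them Pmaip1, Apaf1 and Bax, are also on the p53 list. Among those that fell, singled out after their values were seen, were Xiap and Cycs, and each of these 2 calls ended without at least 5 of the 6 libraries in turn (adjusted p up to 0.155).

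Among genes of the quiescent satellite cell more rose than fell. Of 27 tested, 8 rose and 3 fell, with a median of 0.36 (camera adjusted p = 6.4e-05, and adjusted p = 0.197 with an estimated correlation, so that this call is lost). Rises numbered 10 and falls 3 adjusted over the list alone. Beside Pax7, the lectin-domain protein Chodl rose from 162 ± 17.8 to 925 ± 163 CPM (2.51 ± 0.15, adjusted p = 6.9e-05), the extracellular glutathione peroxidase Gpx3 from 3329.6 ± 370.4 to 7351 ± 506 CPM and the syndecan Sdc4 from 3911 ± 251 to 6087 ± 214 CPM. The members that fell, singled out after their values were seen, were Chrdl2 (-1.06 ± 0.27), an antagonist of bone morphogenetic proteins, and the collagen genes Col5a2 (-0.58 ± 0.14) and Col5a3 (-0.61 ± 0.16), and each of these calls ended without at least 3 of the 6 libraries in turn (adjusted p up to 0.0987). Of 14 satellite cell markers, 6 rose and 3 fell. Rises numbered 7 and falls 6 adjusted over the list alone. Camera placed them higher (adjusted p = 0.00695), a call lost under limma-voom and at adjusted p = 0.414 with an estimated correlation. The markers that fell were Myf5, Itga7 (-0.68 ± 0.12, singled out after its value was seen) and Des (-0.37 ± 0.11). The call of Des ended under 12 of 19 alternatives (adjusted p up to 0.165). It ended whichever library was left out (adjusted p up to 0.134). Among the others were RLE, upper-quartile and library-total scaling and the removal of GC and length trends.

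Among the myogenic factors, Myf5 fell from 449.9 ± 25.6 to 292 ± 18.2 CPM (-0.62 ± 0.078, adjusted p = 0.00136). Myod1, the factor of commitment, stood at 1706 ± 168 CPM in the controls and 1419 ± 68.4 CPM in the iKO-labelled libraries (-0.27 ± 0.08, adjusted p = 0.0511), which misses the threshold. It was past it with DESeq2 (adjusted p = 0.0387), with limma-voom, with limma on filtered log2 FPKM and without control 2 (adjusted p = 0.0283). Myog, the factor of terminal differentiation, was at 6.92 ± 7.99 CPM in the controls and 1.58 ± 1.66 CPM in the iKO-labelled libraries, a difference smaller than the spread of the controls (-2.13 ± 1.38, adjusted p = 0.342) and past the threshold only with no count filter. Of 27 commitment and differentiation genes tested, 5 fell and 1 rose, with a median of -0.62. Rises numbered 1 and falls 8 adjusted over the list alone. Camera placed the list lower (adjusted p = 0.0246), a call lost with the stricter count filter (adjusted p = 0.077) and at adjusted p = 0.181 with an estimated correlation. The acetylcholine receptor subunits Chrna1 (-1.34 ± 0.17) and Chrnb1 (-0.71 ± 0.079) fell, as did Myf5, Des and the skeletal actin Acta1 (-1.84 ± 0.51), while the cadherin Cdh15 rose (0.56 ± 0.09). The call of Acta1 ended without control 1 (log2 fold change -1.22, adjusted p = 0.106) and without each other library but control 3, and that of Des whichever library was left out (adjusted p up to 0.134).

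**Figure D3:**
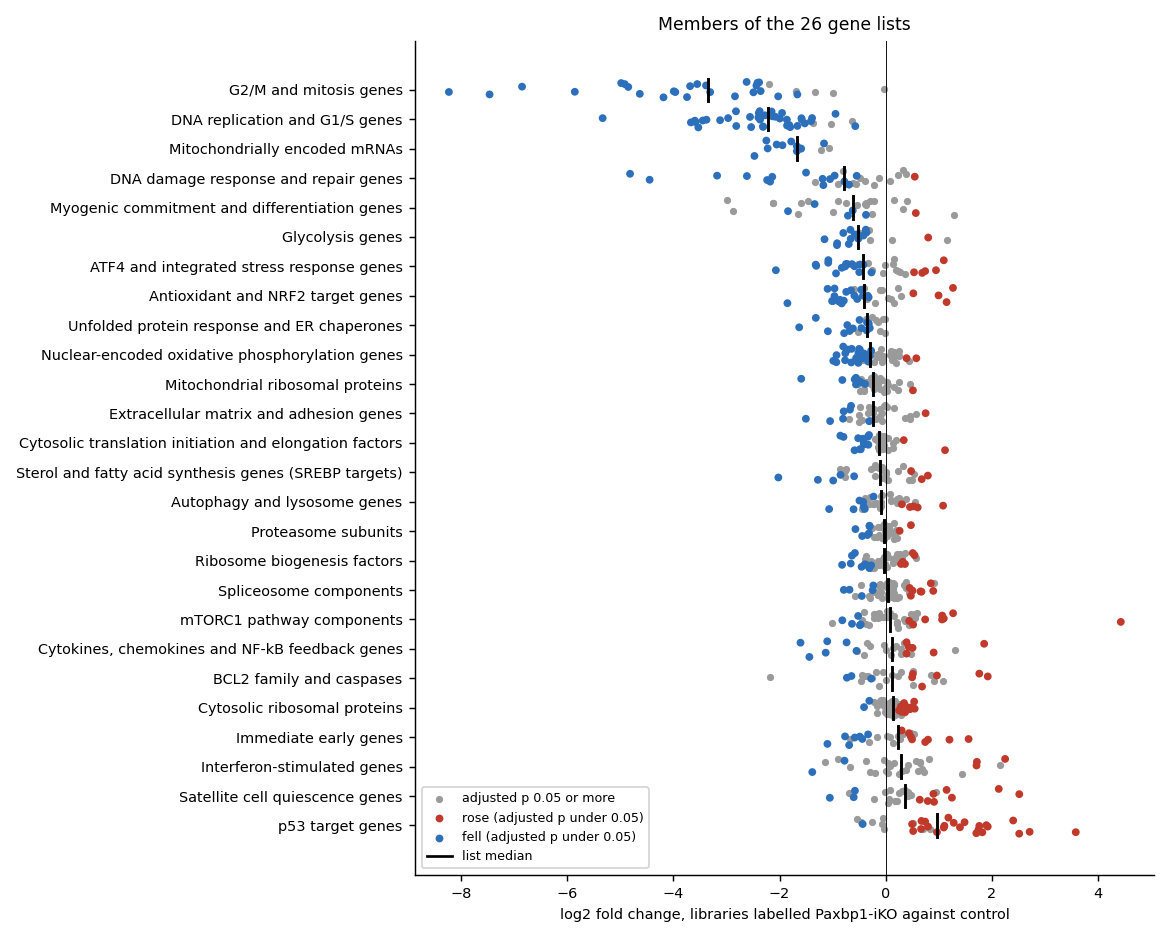
Log2 fold change of the libraries labelled Paxbp1-iKO against control for each tested member of the 26 gene lists fixed beforehand, ordered by list median (black bar), with points spread vertically for legibility. Members past an adjusted p of 0.05 are red where higher and blue where lower, grey otherwise; medians ran from -3.35 for G2/M and mitosis genes to 0.96 for p53 targets.

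Messenger RNAs encoded by the mitochondrial genome were lower. Of 13 tested, 11 fell and none rose, with a median of -1.68 (camera adjusted p = 5.1e-61, and adjusted p = 0.0439 with an estimated correlation). mt-Nd1, a subunit of complex I, fell from 4896 ± 39.2 to 881 ± 36.2 CPM (-2.47 ± 0.052, adjusted p = 6.6e-07), mt-Co1, of cytochrome c oxidase, from 4132 ± 240.0 to 883 ± 41.2 CPM, and mt-Cytb, of complex III, from 4359.8 ± 296 to 1364 ± 43 CPM. mt-Nd3 (-1.07 ± 0.41, adjusted p = 0.11) and mt-Atp8 (-1.22 ± 0.59, adjusted p = 0.197) were the members not past the test, singled out after their values were seen. Rises numbered 0 and falls 12 adjusted over the list alone. Together these messenger RNAs took 1.57% ± 0.067 (SD, n = 3) of the counts in the controls and 0.42% ± 0.0087 in the iKO-labelled libraries. The mitochondrial ribosomal RNAs, singled out after their values were seen, were at 9557 ± 352 CPM in the controls and 10552 ± 1340.3 CPM in the iKO-labelled libraries for mt-Rnr2 (0.14 ± 0.086, adjusted p = 0.301) and at 571 ± 61.5 CPM in the controls and 561 ± 105 CPM in the iKO-labelled libraries for mt-Rnr1 (-0.025 ± 0.14, adjusted p = 0.927). The sign of mt-Rnr1 turns under upper-quartile scaling, scaling by library totals and the stricter count filter, and without control 1 or iKO 3 (0.11), and mt-Rnr2 passes the test under scaling by library totals (adjusted p = 0.0419) and is at -0.092 with GC and length trends removed. Nuclear copies of mitochondrial sequence can share reads with these genes, and how such reads were counted is not given in the sources used here.

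**Figure D4:**
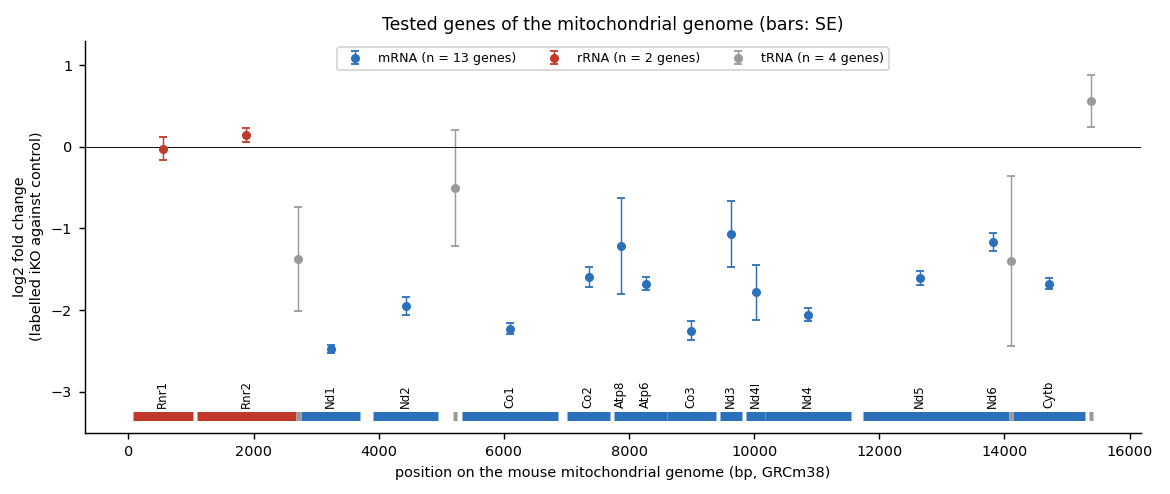
Log2 fold change ± SE of the libraries labelled Paxbp1-iKO against control for the 19 tested genes of the mouse mitochondrial genome, at their positions in GRCm38 (gene models below, colours by kind of RNA). The 13 messenger RNAs lie between -2.47 and -1.07, while mt-Rnr1 and mt-Rnr2 lie at -0.025 and 0.14; the sign of mt-Rnr1 turns under library-total and upper-quartile scaling and that of mt-Rnr2 with GC and length trends removed.

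In each of 3 lists of nuclear genes for energy metabolism and mitochondrial translation more genes fell than rose. Of 51 nuclear-encoded oxidative phosphorylation genes, 23 fell and 2 rose, with a median of -0.30. Rises numbered 3 and falls 27 adjusted over the list alone. The camera call (adjusted p = 2.5e-05) was lost at adjusted p = 0.556 with an estimated correlation. Cyc1, cytochrome c1 of complex III, fell from 299 ± 9.8 to 150.4 ± 5.29 CPM (-0.99 ± 0.072, adjusted p = 1.5e-04), and the succinate dehydrogenase subunits Sdha (-0.93 ± 0.11) and Sdhb (-0.93 ± 0.081) and the ATP synthase subunit Atp5h (-0.77 ± 0.083) fell as well. The risers, singled out after their values were seen, were the complex I subunits Ndufa1 (0.57 ± 0.14) and Ndufa2 (0.39 ± 0.11), neither of them called with GC and length trends removed, nor without at least 5 of the 6 libraries in turn (adjusted p up to 0.132). Of 19 glycolysis genes, 13 fell and 1 rose, with a median of -0.52 (camera adjusted p = 6.6e-08, and adjusted p = 0.0439 with an estimated correlation). Rises numbered 1 and falls 16 adjusted over the list alone. Pkm, pyruvate kinase, fell from 2249 ± 167 to 1009.8 ± 41.1 CPM (-1.16 ± 0.07, adjusted p = 8.1e-05), followed by triose phosphate isomerase Tpi1 (-0.92 ± 0.085), aldolase A Aldoa (-0.54 ± 0.061) and the phosphofructokinase Pfkp (-0.80 ± 0.11), while the lactate exporter Slc16a3 rose (0.80 ± 0.14, singled out after its value was seen). Of 42 mitochondrial ribosomal protein genes, 8 fell, led by Mrpl18 (-1.59 ± 0.15) and Mrpl10 (-0.82 ± 0.13), and 1 rose, Mrps18a (0.51 ± 0.12, singled out after its value was seen and not called without at least 4 of the 6 libraries in turn, adjusted p up to 0.0733). Adjusted over the list alone, 1 rose and 9 fell. The camera call of that list (adjusted p = 0.0164) was lost with the stricter count filter, under scaling by library totals and at adjusted p = 0.414 with an estimated correlation.

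Among antioxidant genes, many of them targets of the transcription factor NRF2, more fell than rose. Of 36 tested, 19 fell and 4 rose, with a median of -0.42 (camera adjusted p = 6.2e-06, and adjusted p = 0.0439 with an estimated correlation). Rises numbered 4 and falls 23 adjusted over the list alone. Thioredoxin reductase, Txnrd1, fell from 2240.2 ± 38.7 to 1110.3 ± 106 CPM (-1.01 ± 0.076, adjusted p = 1.7e-04) and the haem oxygenase Hmox1 from 4698 ± 316 to 2549.9 ± 142 CPM (-0.88 ± 0.066, adjusted p = 1.7e-04). The members that rose encode secreted or membrane-bound enzymes and a glutathione transferase of the cytosol: Gpx3, the extracellular superoxide dismutase Sod3 (1.26 ± 0.10), and, singled out after their values were seen, Mgst1 (0.99 ± 0.13) and Gstm1 (0.52 ± 0.086). Of 22 genes of the unfolded protein response and ER chaperones, 13 fell and none rose, with a median of -0.36. Rises numbered 0 and falls 16 adjusted over the list alone. Dnajc3, an inhibitor of the kinase PERK (-1.09 ± 0.094), the co-chaperone Dnajb11 (-0.79 ± 0.074) and the disulfide isomerases Pdia4 (-1.32 ± 0.13) and Pdia6 (-0.73 ± 0.069) led it. Camera called this list lower (adjusted p = 6.6e-08), lost at adjusted p = 0.106 with an estimated correlation. Of 33 genes of ATF4 and the integrated stress response, 16 fell and 5 rose, with a median of -0.42. Rises numbered 7 and falls 17 adjusted over the list alone. The falls were led by Gars, a transfer RNA synthetase (-1.09 ± 0.07), and by Psat1 (-1.31 ± 0.11) and Phgdh (-1.08 ± 0.11) of serine synthesis. The rises were Nupr1, a stress-induced chromatin protein (0.94 ± 0.081), Ddit4 (1.09 ± 0.11) and Sesn2 (0.74 ± 0.10), which are also on the p53 list, and, singled out after their values were seen, Ddit3 (0.68 ± 0.18) and Ppp1r15a (0.53 ± 0.077), of which Ddit3 was not called without controls 1 or 3 or iKO 1 or 3 (adjusted p up to 0.101). The camera call of the ATF4 list (adjusted p = 0.00604, lower) was lost with the stricter count filter, under scaling by library totals and at adjusted p = 0.442 with an estimated correlation.

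Genes of the mTORC1 pathway, which couples nutrients to growth, moved both ways. Of 41 tested, 8 rose and 5 fell, and camera did not call the list (adjusted p = 0.301). Rises numbered 8 and falls 5 adjusted over the list alone. Those that rose with the smallest p included Ddit4, Sesn2 and Tsc1 (1.06 ± 0.14), known to restrain mTORC1. Those that fell were Eif4ebp1 (-0.64 ± 0.069), a repressor of cap-dependent translation, and, singled out after their values were seen, Rheb (-0.52 ± 0.074), the activating GTPase, its inhibitor Tsc2 (-0.82 ± 0.16), the kinase Akt2 (-0.49 ± 0.089) and the cap-binding protein Eif4e (-0.47 ± 0.072). Mtor itself stood at 29.2 ± 3.45 CPM in the controls and 39.5 ± 4.45 CPM in the iKO-labelled libraries (0.44 ± 0.15, adjusted p = 0.088), past the threshold under upper-quartile scaling, scaling by library totals, the stricter count filter and DESeq2 (adjusted p = 0.0322 with that filter). Of 68 cytosolic ribosomal protein genes, 11 rose and 2 fell, with a median of 0.13. Rises numbered 11 and falls 2 adjusted over the list alone. Rps27 (0.47 ± 0.063), Rps28 (0.54 ± 0.094), Rps29 (0.53 ± 0.10) and Rps15 (0.46 ± 0.083) rose. Those that fell, singled out after their values were seen, were Rpl3 (-0.31 ± 0.079) and Rps12 (-0.41 ± 0.095). They were not called without at least 3 of the 6 libraries in turn (adjusted p up to 0.0928) or, among other alternatives, under scaling by library totals. The camera call of this list (adjusted p = 0.0104, higher) was lost without control 1, control 2 or iKO 1, with GC and length trends removed and at adjusted p = 0.875 with an estimated correlation, and these genes have near-identical pseudogene copies that can share their reads. Of 40 translation factors, 12 fell and 2 rose. Rises numbered 2 and falls 12 adjusted over the list alone. Eif4a2, a helicase of cap-dependent initiation, rose (1.11 ± 0.086), as did Eif4g1 (0.34 ± 0.076, singled out after its value was seen and not called without 4 of the 6 libraries in turn, adjusted p up to 0.0648), while Eif4g2 (-0.44 ± 0.054), Eef1d (-0.59 ± 0.074) and Eif6 (-0.52 ± 0.079) fell. Camera placed the translation factors lower (adjusted p = 0.0231), a call lost under upper-quartile scaling, scaling by library totals, the stricter filter, without the most abundant genes, without iKO 3 and at adjusted p = 0.556 with an estimated correlation.

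The remaining lists were not called by camera. Of 46 ribosome biogenesis factors, 5 rose and 9 fell, the nucleolar chaperone Npm1 (-0.82 ± 0.072), Tcof1 (-0.58 ± 0.085) and Bop1 (-0.66 ± 0.10) falling and the nucleolar GTPase Gnl3 (0.51 ± 0.07) rising. Rises numbered 11 and falls 11 adjusted over the list alone, and camera gave adjusted p = 0.877. Of 31 sterol and fatty acid synthesis genes, 3 rose and 5 fell. Rises numbered 4 and falls 9 adjusted over the list alone, and camera gave adjusted p = 0.28. Nsdhl (-2.02 ± 0.27) and Acat2 (-1.28 ± 0.21) of sterol synthesis and Acly (-0.99 ± 0.13) and Fasn (-0.85 ± 0.15) of fatty acid synthesis fell, and camera passed the threshold with no count filter and without control 3 (adjusted p = 0.0339). Of 52 spliceosome components, 7 rose and 5 fell, with Prpf3 (0.85 ± 0.081) and Srsf7 (0.47 ± 0.063) rising and Snrnp70 (-0.68 ± 0.077) and Eftud2 (-0.79 ± 0.10) falling. Rises numbered 10 and falls 7 adjusted over the list alone, and camera gave adjusted p = 0.426. Of 31 proteasome subunits, 2 rose and 6 fell, among them Psmb3 (0.47 ± 0.092) upward and Psmd1 (-0.57 ± 0.10) downward. Rises numbered 2 and falls 6 adjusted over the list alone, and camera gave adjusted p = 0.711. Of 35 autophagy and lysosome genes, 5 rose and 7 fell, among them the sialidase Neu1 (1.08 ± 0.20) upward and the cathepsin Ctsz (-0.61 ± 0.10) downward. Rises numbered 5 and falls 10 adjusted over the list alone, and camera gave adjusted p = 0.618. The medians of all of these but the spliceosome list change sign under scaling by library totals. Among further members of the small counts, singled out after their values were seen, were Utp4, Polr1c, Nop16 and Ppan (ribosome biogenesis, higher), Hmgcs1 and Lss (higher) and Elovl6 (lower) of lipid synthesis, Prpf31, Sf3b2 and Sf3b4 (splicing, lower), Psmc2 (proteasome, higher) and Gabarap, Atg12 and Atg16l1 (autophagy and lysosome, higher). Apart from Ppan and Prpf31, each of these calls ended without at least 1 library, Nop16 without iKO 3 (adjusted p = 0.0518) and the others without at least 4 of the 6 in turn (adjusted p up to 0.156).

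Signalling and matrix genes also moved both ways. Of 27 immediate early genes, 8 rose and 7 fell. Rises numbered 12 and falls 7 adjusted over the list alone, and camera gave adjusted p = 0.209 though it passed the threshold under scaling by library totals and without control 1, where adjusted p = 0.0192. Zfp36, which destabilises messenger RNAs (0.74 ± 0.069), and the cytokine signalling inhibitor Socs3 (1.20 ± 0.12) rose, and Rhob (-0.77 ± 0.10) and Myc fell. Of 26 cytokine, chemokine and NF-kB feedback genes, 6 rose and 6 fell. Rises numbered 6 and falls 6 adjusted over the list alone. Their median was 0.11 and their mean -0.026, and camera, which put them lower, did not call them (adjusted p = 0.917). Csf1, the macrophage growth factor, fell from 702 ± 50.9 to 259 ± 13.6 CPM (-1.44 ± 0.079, adjusted p = 6.1e-05) and the monocyte chemokine Ccl2 from 287 ± 95.8 to 94.2 ± 7.07 CPM, whereas the chemokine Cx3cl1 rose from 101 ± 28.1 to 365 ± 48.9 CPM and the NF-kB inhibitor Nfkbia from 1370.1 ± 97.5 to 1941 ± 108 CPM. Of 30 interferon-stimulated genes, 3 rose and 2 fell. Rises numbered 3 and falls 2 adjusted over the list alone, and camera gave adjusted p = 0.216. Stat2 (1.71 ± 0.22), Xaf1 (2.24 ± 0.46, not called on unfiltered log2(FPKM + 1)) and Ifit3 (1.71 ± 0.43) rose and Rsad2 (-1.39 ± 0.33) and Cxcl10 (-0.78 ± 0.20, singled out after its value was seen) fell, the last 3 of these not called without 5 of the 6 libraries in turn (adjusted p up to 0.0982). Of 32 extracellular matrix and adhesion genes, 7 fell and 1 rose, with a median of -0.23. Rises numbered 1 and falls 7 adjusted over the list alone. The protease inhibitor Timp1 fell from 218 ± 9.63 to 105 ± 5.03 CPM (-1.05 ± 0.082, adjusted p = 1.9e-04), Lamc1, a laminin chain (-0.79 ± 0.092), and the proteoglycan Bgn (-0.81 ± 0.10) fell, and Col6a1 rose (0.75 ± 0.11). Camera missed the threshold for the matrix list (adjusted p = 0.0551) and passed it under limma-voom, with no count filter, with GC and length trends removed and without control 2, control 3 or iKO 2 (adjusted p = 0.0163 without control 2).

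Markers of 10 other cell types were tested too, and none of their lists was called. Of 16 macrophage and monocyte genes none changed by the main test. Lyz2 stood at 102 ± 32.8 CPM in the controls and 117 ± 42.6 CPM in the iKO-labelled libraries, Cd14 at 72.5 ± 11 CPM in the controls and 87.3 ± 13.6 CPM in the iKO-labelled libraries and Cd74 at 37.9 ± 14.9 CPM in the controls and 67.1 ± 34.5 CPM in the iKO-labelled libraries, the last past the threshold only with no count filter (adjusted p = 0.00274). By the main test none changed of 8 neutrophil, 11 endothelial, 7 tenocyte, 8 Schwann cell, 3 lymphocyte and 4 erythroid genes tested, the last 2 lists being too short for camera. Endothelial genes were most abundant in control 1: Cldn5 had 2550 counts there and 1005 and 477 in the other controls, against 1319, 1603 and 1173 in iKO 1 to 3. Of 13 fibro-adipogenic progenitor genes 1 fell, Fbln1 (-1.46 ± 0.39, adjusted p = 0.034, singled out after its value was seen), a call that ended adjusted over the list alone and without 5 of the 6 libraries in turn (adjusted p up to 0.107), while Gsn stood at 1289 ± 179 CPM in the controls and 1212 ± 73.9 CPM in the iKO-labelled libraries and Col3a1 at 582 ± 94.5 CPM in the controls and 541 ± 64 CPM in the iKO-labelled libraries. Of 9 pericyte and smooth muscle genes 1 fell, the actin Acta2, from 197 ± 55 to 41.9 ± 7.47 CPM (-2.24 ± 0.22, adjusted p = 5.3e-04), while Rgs5 was at 51.3 ± 35.8 and 51.6 ± 15.5 CPM. Of 14 fibre genes 2 fell, the actinin Actn3 (-1.98 ± 0.19, adjusted p = 4.8e-04) and Acta1 (-1.84 ± 0.51, adjusted p = 0.0379), the latter not called without 5 of the 6 libraries in turn (adjusted p up to 0.135), and Ttn, the giant titin, was at 22.8 ± 4.86 and 24 ± 1.87 CPM. Adjusted over the list alone, 0 genes changed on those 7 lists, 1 fell on the pericyte list and 2 on the fibre list. At an unadjusted p under 0.05 edgeR gave 1 neutrophil and 1 tenocyte gene and 0 on the other 5 of those lists, and DESeq2 called 1 neutrophil gene. That gene, Il1b, an inflammatory cytokine (0.89 ± 0.30, adjusted p = 0.0741), also passed with the stricter count filter, library-total scaling and both filtered FPKM fits (lowest adjusted p = 0.0254, with DESeq2), and of the fibro-adipogenic genes Dcn passed with no count filter (adjusted p = 0.037). Median and mean differ in sign for neutrophil genes (-0.051 and 0.12) and tenocyte genes (0.12 and -0.13), and camera put fibro-adipogenic genes higher against a median of -0.089. Camera adjusted p for these lists ran from 0.178 for fibre genes to 0.997 for fibro-adipogenic genes, the fibre list being past the threshold without control 3 (adjusted p = 0.0253) and with no count filter.

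After Stox2, the largest rises named by rule that lie outside these lists were Vsig10 (3.45 ± 0.33), Slc10a6, a transporter of steroid sulfates (3.30 ± 0.67), Neu2, a cytosolic sialidase (3.23 ± 0.23), Dcxr, a reductase of xylulose (3.19 ± 0.56), Arvcf, a catenin of cell junctions (2.97 ± 0.62), Dnah7b, a dynein heavy chain (2.84 ± 0.52), and the zinc finger gene Zfp53 (2.83 ± 0.32). Neu2 went from 52.2 ± 9.98 to 490.3 ± 139 CPM (3.23 ± 0.23, adjusted p = 1.5e-04) and Vsig10 from 7.6 ± 2.89 to 83.6 ± 27.8 CPM (3.45 ± 0.33, adjusted p = 4.8e-04). Spread among the controls was wide for Slc10a6, which rose from 10.4 ± 11.2 to 102 ± 18.4 CPM (log2 fold change 4.68 without control 1), Arvcf, from 4.25 ± 4.08 to 33.5 ± 8.29 CPM (log2 fold change 4.13 without control 3), Dcxr, from 2.73 ± 1.86 to 24.9 ± 4.55 CPM, and Dnah7b, from 2.26 ± 1.55 to 16.1 ± 5.37 CPM. On log2(FPKM + 1) without a filter Dnah7b was not called (adjusted p = 0.0884). Camera called 16 of 35 lists, 4 higher and 12 lower, and 6 of them were also called with an estimated correlation: DNA replication, p53 targets, mitochondrial messenger RNAs, glycolysis, antioxidant genes and DNA repair.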

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

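The alternatives of library-total scaling and of removing GC and length trends were chosen after seeing the data. Paxbp1 stayed higher in the iKO-labelled libraries and past the threshold under every alternative that tests for any change (0.57 to 0.82). Against a 1.5-fold change its rise (0.68) was not called (adjusted p = 0.511). The 3315 changed genes became 817 against a 1.5-fold change and 2053 to 2816 with a library left out. The 1324 higher genes became 2081 with DESeq2 and 706 to 1159 with a library left out. In each alternative fitted to all genes, every gene also called by the edgeR quasi-likelihood test kept its direction. Of the 16 lists called by camera, 6 were called with an estimated correlation. The causes were not tested, except that fewer libraries and a higher bar leave less power by construction. On simulated data with 3 libraries per group, 14.9% of genes planted at 1.5-fold were recovered. Far fewer genes were planted there than were called in the data, so this share need not hold for the data. Some smaller changes were called in the data, such as that of Eif4g2 (-0.44), and others can have been missed.

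With the replicate number as a replicate block, 2215 genes changed, 2176 of them also called without it, 813 higher and 1402 lower. The series text speaks of 3 pairs of mice, without saying what makes a pair or whether the numbers follow the pairs. Samples with the same number did not deviate together (correlations -0.0668, -0.00212 and -0.0593), and 0 libraries correlated best with their own number, a hint from the data and not from the design.

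Other splits of the 6 libraries are too few for a share under 0.05. The real split of 10 gave 3315 changed genes, 1324 higher and 1991 lower, and was for each count the 1 split as large, the highest other split giving 0. For called lists the real split gave 16, the highest other 20, and 4 of 10 splits gave as many. The mixed splits keep part of the group difference, so these list counts cannot decide the question either.

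Of the results for other named genes under alternatives that keep all libraries, 2456 kept direction and side of the threshold, 120 lost and 17 gained a call and 20 changed sign. With a library left out these were 1028, 173, 1 and 22. Every sign change was in a gene without a call by the main test. Library-total scaling gave 0.045 for Gsn, 0.026 for Col3a1, 0.046 for Pmp22, 0.10 for Tagln and 0.11 for mt-Rnr1. Upper-quartile scaling gave 0.046 for Tagln and 0.051 for mt-Rnr1, and the stricter filter 0.036 and 0.043. With GC and length trends removed, S100a8 was at -0.13, Rgs5 at -0.0085, Ttn at -0.33 and mt-Rnr2 at -0.092. Cldn5 was at 0.25 with limma-voom, 0.19 on log2(FPKM + 1) with or without the filter, 0.20 on log2(FPKM + 0.1) and 0.20 with the replicate block. Fabp4 was at 0.019 with limma-voom and 0.0038 on log2(FPKM + 0.1). With each library left out in turn, values ran from -0.059 to 0.51 for Lyz2, -0.17 to 0.19 for S100a8, -1.67 to 8.82 for Ngp, -0.077 to 1.74 for Il7r, -0.22 to 1.37 for Hba-a2, -0.61 to 0.79 for Cldn5, -0.58 to 0.34 for Pecam1, -0.35 to 0.42 for Fabp4, -0.18 to 0.0057 for Gsn, -0.21 to 0.046 for Col3a1, -0.25 to 0.49 for Thbs4, -0.061 to 0.74 for Fmod, -0.39 to 0.66 for Rgs5, -0.12 to 0.087 for Tagln, -0.024 to 0.27 for Ttn and -0.16 to 0.11 for mt-Rnr1.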

Other observations

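Tests chosen only after the result was seen were the gene families, the mitochondrial ribosomal RNAs, reads shared with Synj1, the swap of single libraries, even DNA background in the longer non-coding classes, and GC content and gene length for both groups of non-coding classes. Among 5 gene families taken by symbol, structural genes of chromosomes and the nuclear pore were lower in the iKO-labelled libraries. Of 22 replication-dependent histone genes, which package new DNA, 9 fell and 0 rose (median -1.75, Fisher's exact test against other genes, adjusted p = 0.00113), among them the linker histone Hist1h1c (-1.94 ± 0.35). Their messenger RNAs mostly lack a poly(A) tail, from which Smart-Seq2 starts. Of 21 centromere protein genes, which build the attachment site of the spindle, 10 fell and 0 rose (median -1.77, exact adjusted p = 3.6e-04), among them Cenpi, from 37 ± 8.29 to 4.01 ± 1.24 CPM. Of 20 nucleoporin genes, 9 fell and 0 rose (median -0.36, exact adjusted p = 7.2e-04), among them Nup85, from 183 ± 15.8 to 77.4 ± 1.79 CPM. Zinc finger genes named Zfp (38 rose and 9 fell of 336, exact adjusted p = 0.0536) and protocadherin genes (3 rose and 0 fell of 52, exact adjusted p = 0.798) missed the threshold. The named genes of these families were singled out after their values were seen. The exact tests took each family's direction from its own median and treated genes as independent, so their p-values overstate the evidence and only describe these values.

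The fall of the mitochondrial messenger RNAs was set against 4 explanations. Fewer mitochondria or less mitochondrial DNA would lower the ribosomal RNAs alike, but their mean was 0.059 (SE 0.082) against a median of -1.68. This argues against it only as far as counts of the ribosomal RNAs follow their amounts. No scaling brought the median of the messenger RNAs above -1.54. Reads shared with nuclear copies limit the comparison with the ribosomal RNAs. So does the start from the poly(A) tail, since how well it captured the ribosomal RNAs in each group is not known. Nuclear-encoded oxidative phosphorylation genes were also lower, though by less (23 of 51 fell and 2 rose, median -0.30). Genes of the mitochondrial transcription machinery had a median of 0.029 over 10 genes, against a general loss of that machinery. That median includes Mterf1a, Mterf1b and Mterf2 (2.11, 1.42 and 1.36), which had few counts and were not called. Polrmt (0.060 ± 0.21), Tfam (-0.20 ± 0.10) and Tfb2m (-0.0032 ± 0.11) were not called either. Tefm, its elongation factor, fell (-1.07 ± 0.30) and Mterf4 rose (0.83 ± 0.22). Both calls ended without 5 of the 6 libraries in turn (adjusted p up to 0.117). A median cannot show the effect of 1 limiting factor, so lower Tefm stays open. Lrpprc, whose protein with that of Slirp keeps most of these messenger RNAs stable and adenylated, fell by 1.28 on the log2 scale (-1.28 ± 0.14), while Slirp was at 0.18 ± 0.16, so lower Lrpprc is a candidate explanation. mt-Nd6, on the minus strand and singled out after its value was seen, fell too (-1.16 ± 0.11). Reads counted for it can come from either strand, so whether lower Lrpprc bears on it cannot be told. Shorter tails could also lower capture by Smart-Seq2 without fewer molecules, which stays open, as does any other technical cause in library preparation, which was not tested, and an effect of losing Paxbp1 itself cannot be separated from the groups.

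The higher whole-gene counts of Paxbp1 in the libraries labelled Paxbp1-iKO were set against 2 technical explanations. Reads shared with Synj1, 1 of 3 tested genes within 50 kb, would raise it alike, but it was at 0.017 ± 0.22, below Paxbp1 by 0.67 (SE 0.26), which argues against it. For the other neighbours this cannot be told apart from a change of Paxbp1, as few counts left 4932438H23Rik at 0.41 ± 1.32 and the overlapping 4930404I05Rik at -0.23 ± 0.68. A swap of single libraries is argued against, since 0 of 6 libraries correlated as well with the other group as with their own. An exchange of all labels stays open, as does a transcript that lacks the floxed exons but is made or kept at a higher level; counts per exon are not analysed here.

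Genes of 9 non-coding RNA classes were higher: of 1641 tested, 143 rose and 4 fell. Of 13349 protein-coding genes 1157 rose and 1910 fell, so the shares called higher were alike and the non-coding classes differed by fewer falls. The non-coding genes had a median of 0.59, and 73.2% of them lay above 0, against 49.0% of the protein-coding genes. Of 10000 sets of protein-coding genes matched on level, 0 had a median as high (highest 0.39). Low expression therefore does not account for all of the rise. It goes with part of it, as the typical matched set was at 0.23, against -0.016 for all protein-coding genes. Sets matched on level and exon length were typically at 0.18 and did not exceed 0.32, against 0.56 for the longer classes. This argues against DNA background spread evenly over the genome as the whole cause for those. Background in general cannot be told apart from an RNA change: control 1, with receptor reads at 40.3 CPM (iKO-labelled libraries 22.0 to 39.7), had a non-coding deviation of -0.11 against at least 0.41, but it is 1 library, and controls 2 and 3 had less background than every iKO-labelled library (12.2 CPM in control 2) and lower deviations than control 1 (-0.16 and -0.44). Host genes were tested only for 187 intronic small and sense-intronic RNAs, of which 78.1% lay above their host (host median -0.027), against rising hosts for these. With GC and length trends removed, the longer classes kept a median of 0.48 (SE 0.04), which argues against those trends as the whole cause, whereas the small RNA classes went from 0.77 to 0.32 (SE 0.13), so for these the trend and an RNA change cannot be told apart, their exon lengths lying far below the other genes. A larger share of unspliced or antisense reads in the iKO-labelled libraries may account for the rest and stays open, since Smart-Seq2 does not mark the strand.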
